A study of Mus musculus with 12 samples.

How the data were processed

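RNA was measured in 12 retina libraries of C57BL/6 mice at postnatal day 17, 6 from normoxic and 6 from OIR mice, per the labels. Total RNA was extracted and poly-A RNA was captured with oligo-dT, per the labels' protocols. Trimmomatic, HISAT2 version 2.0.5, HTSeq and genome build GRCm39 are named, without their roles or order, per the submitters' processing notes. The annotation release, the strand setting of the counting and filters on reads are not given in the sources used here. The authors deposited 1 table with whole-number counts per gene and, beside them, FPKM (fragments per kilobase of gene, scaled to library depth), per the file headers. The deposited FPKM equalled the count scaled by the library total and by a gene length. This length was the same in every library within 5.4e-05 percent, equalled the length column within 0.1% for 47.1% of the genes with counts and was further below it for 52.9%. How a gene's length was chosen is not given in the sources used here, and it cancels in a comparison of the same gene between groups. Of 57073 gene models, 1657 had no Ensembl identifier and names starting with XLOC, of which 1177 were tested and 228 passed the test.

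Groups and replicate numbers were taken from the sample titles. The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where a test or gene is said to have been chosen later. That design named limma on FPKM as the main test unless the table held counts. Since it did, the counts were tested with edgeR version 4.0.16 (R version 4.3.3): filterByExpr with a minimum count of 10 and total of 15, TMM scaling, and the quasi-likelihood test with Benjamini-Hochberg adjustment, with an adjusted p of 0.05 as threshold. Adjusted p-values called edgeR's are from this test. Levels are CPM (counts scaled to a common library total) as mean ± SD over 6 libraries, and log2 fold changes are OIR minus normoxic with their SE. For genes with at most 20 counts summed over a group, a ratio of counts with a 95% counting interval is given, which covers counting error only. Each library was counted as 1 sample, as the labels list it. Pairs of libraries in a group differed beyond sampling noise (chi-square per degree of freedom 3.06 to 15.6), so no pair was merged as a repeat deposit of 1 library, which does not show that the libraries came from separate animals.

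Lists were tested with camera in limma version 3.58.1 (preset correlation 0.01, and again with an estimated correlation), adjusted over 32 lists. They covered hypoxia-inducible targets, glycolysis, endothelium, tip cells, barrier genes, pericytes, matrix, Müller glia, gliosis, microglia, cytokines, complement, rods, cones, bipolar, amacrine, ganglion and horizontal cells, proliferation, astrocytes, interferon response, p53, unfolded protein response, oxidative phosphorylation, oxidative stress, cholesterol synthesis, lens, pigment epithelium, red blood cells, immediate early genes, clock genes and mitochondrial mRNAs. Annotation terms of the table with 10 to 500 tested genes were tested with a one-sided Fisher's exact test against the tested genes. Mean list levels and composition measures were compared with exact two-sided permutation tests over 924 assignments.

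Named genes were the 10 with the highest and the 10 with the lowest log2 fold change among genes past the threshold, with a mean FPKM of at least 1 in a group and groups that did not overlap. Gene models without a proper name were skipped, and since the table gives no biotype, genes that do not code for protein were not. To these were added the 3 members of each primary list and the 1 member of each secondary list with the smallest adjusted p, up to 5 where no more passed, and genes named in any case, of which 1 is not reported here. Principal components and correlations used log2(FPKM + 1).

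Alternatives were other expression filters, median-of-ratios factors, robust dispersion, a block for the replicate number, a lens covariate, DESeq2 version 1.42.0, leaving out each library, and limma on log2(FPKM + 1) with other pseudocounts (0.1 and 0.5), filters and scalings. Comparisons within replicate numbers 1 to 3 and within 4 to 6, a block for these sets and scaling by library totals only were chosen after seeing the data. GC content came from transcripts of another build, GRCm38, matched by Ensembl identifier for 93.2% of the genes, and no coordinates of that build were used. The procedure was tested on simulated data for OIR against normoxic with 18077 genes. It recovered 22% of 50 genes changed 1.25-fold, 58% at 1.5-fold, 78% at 2-fold and 98% at 4-fold, with 4 false calls (3.03% of the calls). It called 0 genes, 0 lists and 0 terms where nothing had been changed. The simulation drew each gene independently and without sets inside a group. It therefore does not cover false calls of lists and terms whose genes vary together. Total counts per library of 17361979 to 21594618 limit what can be said of genes with few counts.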

Results

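Retinas of C57BL/6 mice were collected at postnatal day 17 and profiled by RNA sequencing of poly-A transcripts. The 12 libraries formed 2 groups of 6, one from mice kept in normoxic air and one from mice with oxygen-induced retinopathy (OIR), for which the labels give 75% oxygen. In this model, pups kept in high oxygen lose part of their retinal capillaries, and after the return to room air the poorly perfused retina becomes hypoxic and grows abnormal new vessels. Total counts per library ranged from 17361979 to 19390627 in the normoxic group and from 17366045 to 21594618 in the OIR group. Between 25009 and 26096 genes had at least 1 count in a library, and the median biological coefficient of variation was 11.2%. Xist, transcribed from the inactive X chromosome, and Ddx3y, a Y-linked gene, were both counted in every library, at 321 to 1350 and 8.46 to 60.8 CPM (counts scaled to a common library total). Their presence in every library argues that each held RNA of both sexes, and so of more than 1 animal. Ddx3y ranged from 20 to 60.8 CPM in normoxic and from 8.46 to 43.3 CPM in OIR libraries. This argues against all 6 libraries of a group repeating 1 RNA pool, though some may share animals. The labels do not say that the libraries of a group came from separate animals. The p-values measure the spread between these libraries, which may be partly technical.

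The comparison asked how the retinal transcriptome of OIR mice differed from that of age-matched normoxic mice. Vegfa, which encodes the main hypoxia-induced growth factor of endothelial cells (chromosome 17, 46327919 to 46343295 in build GRCm39), rose from 228 ± 9.59 to 521 ± 54.0 CPM (mean ± SD, n = 6 in each group). This was a 2.28-fold rise, with a log2 fold change of 1.19 ± 0.06 (SE) and an edgeR adjusted p of 9.7e-11. Gfap, an intermediate filament gene of astrocytes and stressed Müller glia (chromosome 11, 102778162 to 102791738), rose 13.7-fold, from 16.4 ± 3.6 to 225 ± 63.9 CPM (edgeR adjusted p = 4.7e-11). Esm1, a gene of endothelial tip cells (chromosome 13, 113346193 to 113354632), had 5 counts summed over the normoxic libraries and 1145 over the OIR libraries, a ratio of counts of 227 (95% counting interval 97 to 700). Of the 5 normoxic counts, 3 came from replicate 6. Edn2, which encodes a peptide of the endothelin family (chromosome 4, 120018403 to 120024557), rose from 1.28 ± 1.06 to 95.8 ± 50.1 CPM (edgeR adjusted p = 6.4e-09). Its level was 104 to 177 CPM in OIR replicates 1 to 3 and 32.3 to 75.9 CPM in OIR replicates 4 to 6. Gfap parted likewise, at 224 to 313 against 150 to 192 CPM, while Vegfa and Esm1 overlapped between these replicates.

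Angpt2, a destabilising ligand of the endothelial Tie2 receptor, rose 4.87-fold (log2 2.28 ± 0.14 SE, edgeR adjusted p = 8.9e-10). The endothelial adhesion molecule gene Pecam1 rose 2.44-fold (edgeR adjusted p = 1.4e-09). Aif1, which encodes the microglial marker Iba1, rose 3.24-fold from a low level of 0.724 ± 0.214 CPM (edgeR adjusted p = 1.8e-04). For each of these genes, the 6 OIR libraries all lay above the 6 normoxic libraries.

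**Figure D1:**
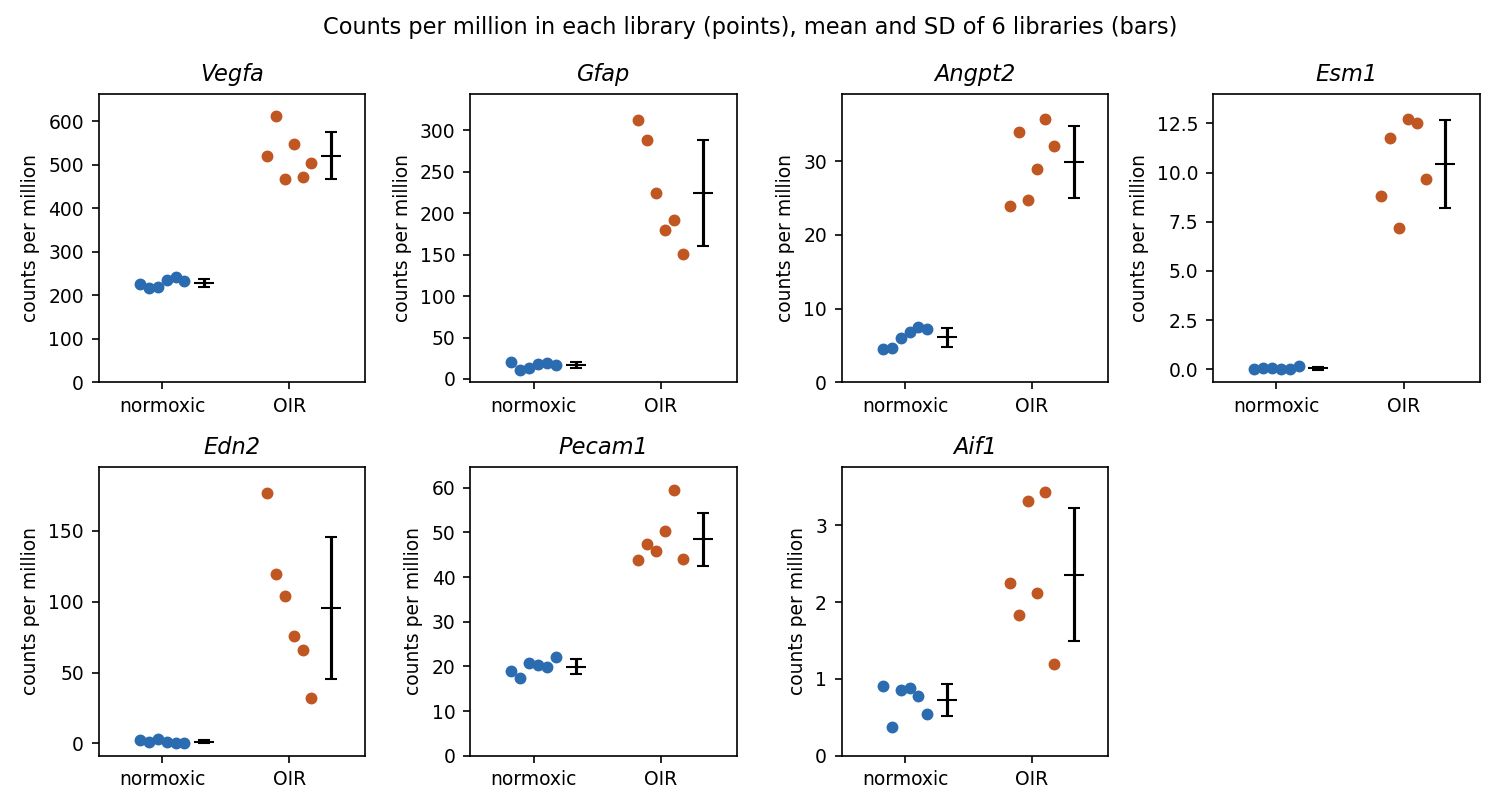
CPM (vertical axes, linear; counts scaled to a common library total) of Vegfa, Gfap, Angpt2, Esm1, Edn2, Pecam1 and Aif1, with 1 point per library and bars for the mean and SD of the 6 libraries of each group. The normoxic and OIR points do not overlap for any of these genes, with Vegfa at 228 against 521 CPM and Gfap at 16.4 against 225 CPM on average.

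Of 18275 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5673 (31.0%) passed an adjusted p of 0.05. Of these, 2969 (52.3%) were higher and 2704 lower in OIR. At least 2-fold differences were found in 1052 genes, of which 896 (85.2%) were higher and 156 lower. The libraries of the 2 groups did not overlap in 2938 of the tested genes, 16.1% of them, where chance gives 0.216%. Among the list members and the genes of the naming rule for which a fold change or ratio is reported, the groups overlapped in Ttr, Slc24a1, Gngt1, Pde6a, Pde6b, Arr3, Pax2, Agt, Glul, Slc1a3, Clu, Pfkm, Herpud1, Acsl4, Fosb, Dbp, Uqcrfs1, Cyc1, Alas2, Hba-a1, Hbb-bs and Hbb-bt, and in each other one the 6 OIR libraries all lay on the same side of the 6 normoxic ones. With the lens gene level as a covariate, 3443 genes passed, and of 121 genes followed through the alternatives 17 lost their call and 1 reversed. The mean lens gene level itself differed between the groups, 1.28 in normoxic and 0.771 in OIR libraries (log2 FPKM plus 1). The covariate therefore takes up part of the group difference, and a call lost with it cannot be put down to lens RNA.

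Fold changes were ranked among properly named genes past the threshold with a mean FPKM of at least 1 in a group and groups that did not overlap. The 10 highest in this ranking were Esm1, Ccl2, Edn2, Serpina3n, Hmox1, Kcne3, Adm, Actg2, Lad1 and Bcl3. Ccl2, a monocyte chemokine gene, had 2 normoxic counts, both in replicate 3, against 207 in OIR, a ratio of 103 (95% counting interval 28 to 853). The ion channel subunit gene Kcne3 and the smooth muscle actin gene Actg2 had ratios of 26.9 (13.9 to 59.5) and 23.7 (14.1 to 42.7). Serpina3n, an acute-phase protease inhibitor gene of a family with near-identical members and therefore less certain, rose 34.1-fold. Hmox1, the heme oxygenase gene, rose 26.1-fold (2.28 ± 0.611 to 59.8 ± 17.5 CPM, edgeR adjusted p = 4.6e-11), and the vasodilator peptide gene Adm rose 22.7-fold. Lad1, a basement membrane anchoring gene, and Bcl3, a regulator of NF-kB transcription, rose 22.2-fold and 20-fold.

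The 10 most negative fold changes in the same ranking were those of P2rx2, Cck, Cidea, Traip, Olfm4, Mypn, Smim18, H2-M5, Sec14l5 and Dbhos. P2rx2, an ATP-gated channel gene, fell by 2.06 ± 0.22 (SE) on the log2 scale, from 6.35 ± 1.90 to 1.51 ± 0.424 CPM (edgeR adjusted p = 1.2e-06). Cck, the cholecystokinin gene used as an amacrine cell marker, fell by 1.91 ± 0.19 (edgeR adjusted p = 4.0e-07). Traip, a ubiquitin ligase gene, fell by 1.31 and Olfm4, which encodes a secreted glycoprotein, by 1.20. Cidea, a lipid droplet gene, fell by 1.41, while Mypn, Smim18 and Sec14l5 had log2 fold changes of -1.13, -1.09 and -1.07. In Sec14l5, OIR replicate 2 stood apart at 4.13 CPM. H2-M5 (-1.08), one of many similar histocompatibility genes, is uncertain. So is Dbhos (-1.06, edgeR adjusted p = 0.00348), an antisense gene whose reads cannot be told from those of its partner without strand. The call of Dbhos was lost within replicate numbers 4 to 6 (adjusted p = 0.221).

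The libraries separated by group on the first principal component (51.4% of the variance). On the second (13.6%), normoxic replicates 1 to 3 lay at 12.5 to 15.2 and normoxic replicates 4 to 6 at -18.4 to -13.1, so comparisons were also made within replicate numbers 1 to 3 and within 4 to 6. OIR replicate 6 stood alone on the third component (6.50%), at 23.4. Pearson correlations between libraries (log2 FPKM plus 1, across genes, which are not independent replicates) were 0.993 to 0.994 within either set of normoxic replicates, 0.985 to 0.988 between these sets, 0.987 to 0.993 within OIR and 0.967 to 0.981 between groups. Mitochondrially encoded counts were 3.57 ± 0.324% of the total in normoxic and 3.00 ± 0.162% in OIR libraries (exact two-sided permutation test, p = 0.00216, the smallest 924 assignments can give; adjusted p = 0.013 over 6 tests). By the same exact test, the mean level of lens genes was lower in OIR by a log2 difference of -0.51 (p = 0.0195, adjusted p = 0.0292), that of red blood cell genes higher by 0.45 (p = 0.0108, adjusted p = 0.0216) and that of mitochondrial mRNAs lower by -0.24 (p = 0.00433, adjusted p = 0.013). In the same exact permutation tests, the pigment epithelium mean differed by 0.20 (p = 0.45, adjusted p = 0.54) and the table total by -818 FPKM (p = 0.623, adjusted p = 0.623).

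**Figure D2:**
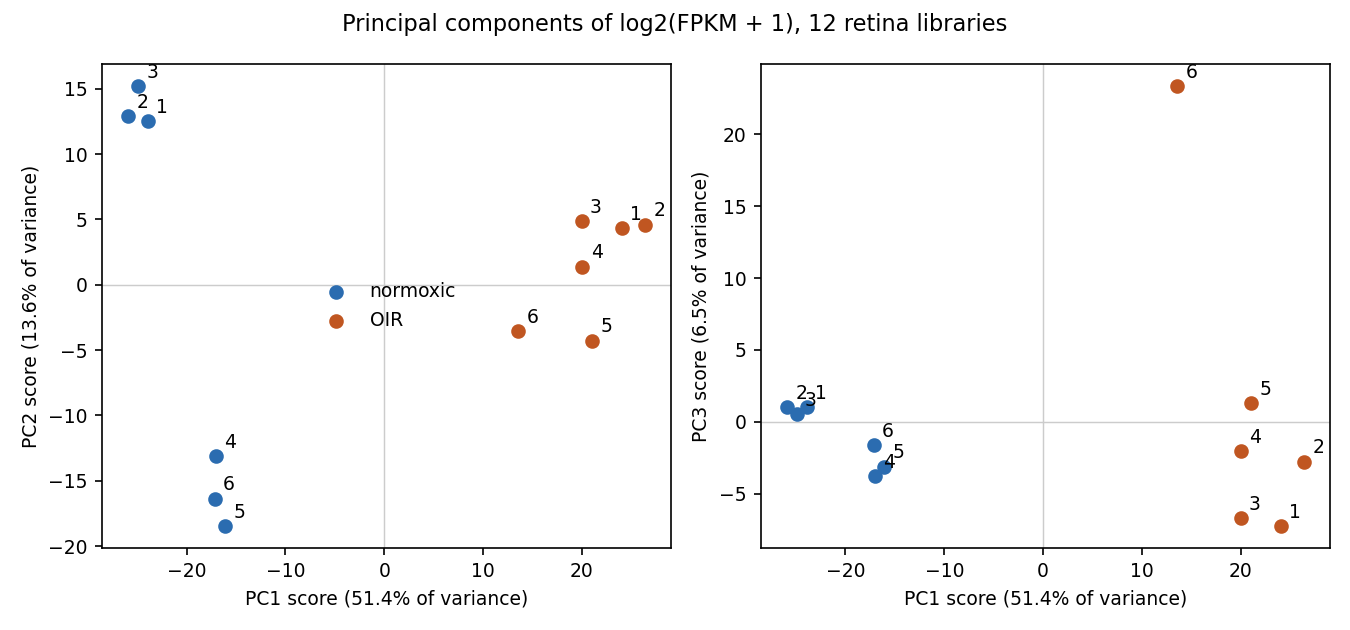
Principal components of log2(FPKM + 1) of the tested genes, 1 point per library, with normoxic and OIR libraries in different colours and axes in component scores. The first component (51.4% of the variance) parts the groups, the second (13.6%) parts normoxic replicates 1 to 3 from 4 to 6, and the third (6.50%) sets OIR replicate 6 apart.

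Targets of the hypoxia-inducible transcription factors rose together in OIR. Of 27 tested members, 23 rose, none fell and 4 did not pass the test (25 rose when adjusted over the list alone). Adm rose 22.7-fold as above. Egln3, a prolyl hydroxylase that marks the factor for degradation, rose 9.57-fold, with OIR replicate 2 above the rest at 39.7 CPM. Stc2, a secreted glycoprotein gene, rose 4.87-fold. The median log2 fold change of the list was 0.86, with 0.87 within replicate numbers 1 to 3 and 0.88 within 4 to 6 (limma's camera test with a preset correlation, adjusted p = 1.5e-40; adjusted p = 3.3e-04 with an estimated correlation).

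Of 17 glycolysis genes, 13 rose, 1 fell and 3 did not pass (13 and 2 when adjusted over the list alone), with a median log2 fold change of 0.40. The lactate exporter gene Slc16a3 rose 2.11-fold, and Pgk1 and Pgam1, which encode enzymes of the lower pathway, rose 1.44-fold and 1.39-fold (edgeR adjusted p = 7.0e-07, 8.3e-08 and 3.5e-07). The member that fell was Pfkm, the muscle-type phosphofructokinase, by 0.38 on the log2 scale (chosen after its values were seen; adjusted p = 0.0613 within numbers 4 to 6). The list was called higher (camera adjusted p = 1.1e-07), with an adjusted p = 0.139 with an estimated correlation. Its medians were 0.36 within numbers 1 to 3 and 0.52 within 4 to 6. Several glycolysis genes have processed pseudogenes, so their counts are less certain.

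Endothelial cell markers rose in 17 of 18 members, with none falling (18 when adjusted over the list alone). The von Willebrand factor gene Vwf rose 3.85-fold, the junctional cadherin gene Cdh5 3.40-fold and Pecam1 2.44-fold (edgeR adjusted p = 1.1e-09, 2.1e-09 and 1.4e-09). The median was 1.27 on the log2 scale, and 1.22 and 1.35 within numbers 1 to 3 and 4 to 6 (camera adjusted p = 1.1e-26; 0.00773 with an estimated correlation). Tip cell and sprouting genes rose in 15 of 15 members (also 15 when adjusted over the list alone), with a median of 2.21. Apln, a peptide ligand gene of sprouting vessels, rose 16.0-fold (6.77 ± 3.58 to 109 ± 16.0 CPM), beside Esm1 and Angpt2. This list had medians of 2.55 and 1.89 within the 2 sets of numbers (camera adjusted p = 1.7e-33; 0.00422 with an estimated correlation).

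Pericyte and smooth muscle markers rose in 11 of 11 tested members, over all genes and when adjusted over the list alone. The smooth muscle actin gene Acta2 rose 9.95-fold, the desmin gene Des 4.19-fold and the pericyte marker Rgs5 2.76-fold. The list median was 1.32, with 1.22 and 1.43 within numbers 1 to 3 and 4 to 6 (camera adjusted p = 1.3e-21; 0.00301 with an estimated correlation). Extracellular matrix genes rose in 17 of 19 members, with none falling (17 when adjusted over the list alone). The basement membrane collagen genes Col4a1 and Col4a2 rose 4.80-fold and 3.46-fold (edgeR adjusted p = 6.3e-13 and 3.8e-12), and the crosslinking enzyme gene Loxl2 rose 4.21-fold. The matrix list had a median of 1.79, and 1.91 and 1.75 within the sets of numbers (camera adjusted p = 3.4e-58; 1.5e-04 with an estimated correlation).

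Blood-retina barrier and Norrin signalling genes had a smaller list median than the lists above, a difference that was not tested. Of 16 members, 9 rose, 1 fell and 6 did not pass (10 and 1 when adjusted over the list alone). Lrp5 and Fzd4, which encode the Norrin co-receptor and receptor, rose 1.92-fold and 1.54-fold, and the tight junction gene Cldn5 1.72-fold (edgeR adjusted p = 1.2e-07, 3.1e-05 and 3.0e-05). The member that fell was Slco1c1, a thyroid hormone transporter gene, by 0.70 on the log2 scale (chosen after its values were seen; adjusted p = 0.0783 within numbers 4 to 6). The list median was 0.36, and 0.32 within either set of numbers (camera adjusted p = 0.0038), with adjusted p = 0.118 with an estimated correlation and 0.0781 with a mean FPKM of at least 2 required. That filter left out Lrp5, so only part of the list was tested there.

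**Figure D3:**
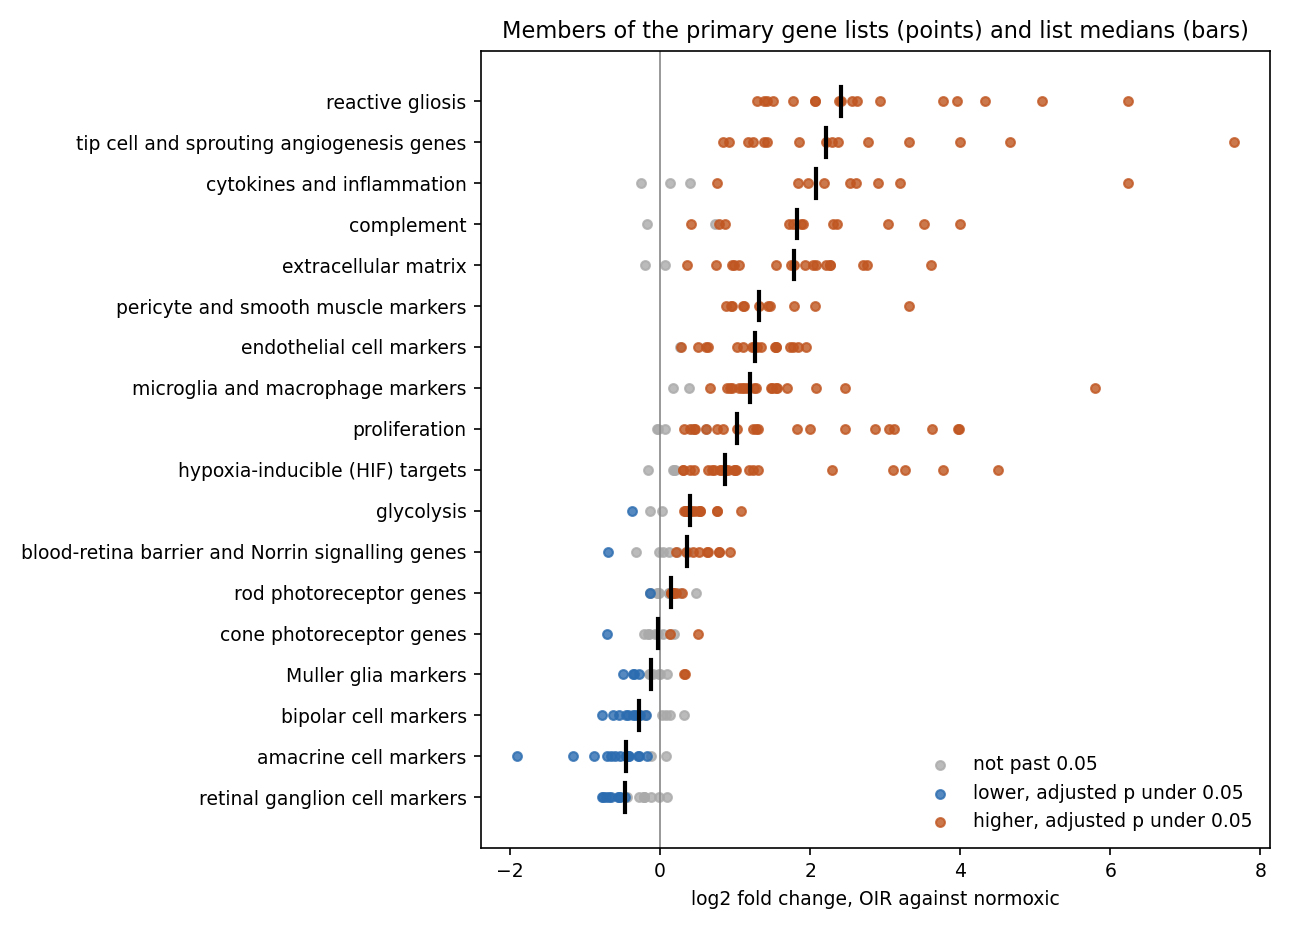
Log2 fold changes, OIR against normoxic (horizontal axis), of the tested members of the primary gene lists, with 1 point per gene coloured by its edgeR call and a bar at the list median. Gliosis (median 2.41), tip cell (2.21) and matrix genes (1.79) lie to the right, while amacrine (-0.45) and ganglion cell markers (-0.47) lie to the left.

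Reactive gliosis genes rose in 17 of 17 members, over all genes and when adjusted over the list alone, with a median log2 fold change of 2.41. Beside Gfap and Serpina3n, the intermediate filament gene Vim rose 2.68-fold, from 228 ± 17.3 to 611 ± 64.2 CPM (edgeR adjusted p = 5.4e-11). The median was 2.91 within numbers 1 to 3 and 1.90 within 4 to 6 (camera adjusted p = 2.3e-40; 0.00442 with an estimated correlation). The Muller glia markers went both ways. Of 12, Slc1a3 (0.33) and Clu (0.32) rose and 4 fell (2 and 5 when adjusted over the list alone). Those that fell were the lipid transporter gene Abca8a (-0.50), the water channel gene Aqp4 (-0.35), the retinaldehyde-binding gene Rlbp1 (-0.36) and the glutamine synthetase gene Glul (-0.28). Slc1a3, a glutamate transporter gene, Clu and Glul were chosen after their values were seen. Slc1a3 and Glul were not past the test within numbers 4 to 6 (adjusted p = 0.297 and 0.819) or with the lens covariate (0.127 and 0.237). The list did not pass (median -0.12, camera adjusted p = 0.1; 0.389 with an estimated correlation). Within numbers 1 to 3 it was called lower (median -0.18, camera adjusted p = 0.00715), and within 4 to 6 it was not (median 0.00, adjusted p = 0.72, test lower), while without an expression filter it passed (0.0386).

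Astrocyte markers rose in 5 of 6 members (also 5 when adjusted over the list alone), namely the gap junction gene Gja1 (4.24-fold), Pdgfra (2.24-fold), Pax2 (2.04-fold), Aldh1l1 (1.68-fold) and Agt (1.30-fold). The median over members was 0.89, and 1.14 and 0.77 within the sets of numbers (camera adjusted p = 6.2e-04; 0.0402 with an estimated correlation). Pax2 was not past the test within numbers 4 to 6 (adjusted p = 0.136) or with the lens covariate (0.056), nor Agt within 1 to 3 (0.0628).

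Microglia and macrophage markers rose in 18 of 20 members, with none falling (19 when adjusted over the list alone). Mrc1, the macrophage mannose receptor gene, had 6 normoxic and 373 OIR counts, a ratio of 61.6 (95% counting interval 28 to 169). The lysosomal membrane gene Laptm5 rose 2.81-fold, with OIR replicate 6 below the rest at 16.2 CPM, and the colony-stimulating factor receptor gene Csf1r rose 1.95-fold. The list median was 1.20, with 1.32 and 1.12 within the sets of numbers (camera adjusted p = 2.4e-20; 0.00301 with an estimated correlation). Complement genes rose in 12 of 14 members, with none falling (13 when adjusted over the list alone). C1qb and C1qc, subunits of the first component, rose 3.66-fold and 3.76-fold, and the C1 inhibitor gene Serping1 rose 5.14-fold (edgeR adjusted p = 9.7e-11, 1.9e-09 and 5.9e-09). The complement list had a median of 1.82, and 1.75 and 1.84 within the sets of numbers (camera adjusted p = 2.3e-18; 0.00358 with an estimated correlation).

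Genes of the list of cytokines and inflammation rose in 9 of 12 tested members, with none falling (10 rose and 1 fell when adjusted over the list alone). Beside Ccl2, the galectin gene Lgals3 rose 6.10-fold and the pattern receptor gene Tlr2 4.52-fold (edgeR adjusted p = 8.0e-09 and 1.3e-05). The median was 2.08, and 2.36 and 1.95 within the sets of numbers (camera adjusted p = 5.3e-08; 0.017 with an estimated correlation). With the genes limited to a mean FPKM of at least 2, the list did not pass (adjusted p = 0.0745). That limit left out Ccl2 and Tlr2, so only part of the list was tested there. Type I interferon response genes rose in 11 of 15 members, with none falling (11 when adjusted over the list alone). Irf7, an interferon regulatory factor gene, rose 1.85-fold (edgeR adjusted p = 2.2e-07). The interferon list median was 0.87, and 0.81 and 1.13 within the sets of numbers (camera adjusted p = 4.6e-05), with adjusted p = 0.243 with an estimated correlation. OIR replicate 6 had a lower mean level of these genes than the other OIR libraries, 2.23 against 3.19 for the nearest (log2 CPM), and lay within the normoxic range of 1.63 to 2.64.

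Proliferation genes rose in 20 of 25 members, with none falling (21 when adjusted over the list alone). The DNA topoisomerase gene Top2a rose 15.6-fold from 0.468 ± 0.272 CPM, Cdk1 8.27-fold and the replication licensing gene Mcm3 3.98-fold (edgeR adjusted p = 6.5e-09, 4.2e-07 and 2.5e-07). In Cdk1, normoxic replicate 5 stood above the other normoxic libraries at 2.00 CPM. Its median was 1.03, and 0.92 and 0.93 within the sets of numbers (camera adjusted p = 1.3e-13; 0.00965 with an estimated correlation). With a mean FPKM of at least 2 required, the list did not pass (adjusted p = 0.125). That filter left out Top2a, Cdk1 and Mcm3, so only part of the list was tested there.

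Markers of inner retinal neurons were lower in OIR. Amacrine cell markers fell in 15 of 17 members and none rose, over all genes and when adjusted over the list alone. Beside Cck, the GABA synthesis gene Gad1 fell by 0.71 ± 0.09 (SE) on the log2 scale and the transcription factor gene Pax6 by 0.29 ± 0.04 (edgeR adjusted p = 1.2e-05 and 1.8e-05). The median over members was -0.45, and -0.67 and -0.28 within numbers 1 to 3 and 4 to 6 (camera adjusted p = 4.6e-08; 0.0402 with an estimated correlation). The log2 fold change of Cck was less negative within numbers 4 to 6 than within 1 to 3, by 0.96 (edgeR interaction adjusted p = 0.00717).

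Bipolar cell markers fell in 11 of 17 members and none rose, over all genes and when adjusted over the list alone. The glutamate receptor gene of ON bipolar cells, Grm6, fell by 0.77 ± 0.07 (317 ± 35.9 to 186 ± 14.5 CPM, edgeR adjusted p = 1.8e-07), with OIR replicate 1 below the rest at 157 CPM. The calcium-binding protein gene Scgn fell by 0.63 and the kainate receptor gene Grik1 by 0.54. The bipolar list median was -0.28, and -0.37 and -0.21 within the sets of numbers (camera adjusted p = 1.2e-05), with adjusted p = 0.13 with an estimated correlation. Retinal ganglion cell markers fell in 9 of 17 members and none rose (also 9 when adjusted over the list alone). The nicotinic receptor gene Chrna6 fell by 0.77 ± 0.06, with OIR replicate 6 above the rest at 95.1 CPM, and the neurofilament genes Nefl and Nefh fell by 0.65 and 0.54 (edgeR adjusted p = 3.5e-08, 9.0e-06 and 2.3e-07). The ganglion cell list median was -0.47, and -0.24 and -0.56 within the sets of numbers (camera adjusted p = 1.1e-05), with adjusted p = 0.243 with an estimated correlation.

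Horizontal cell markers fell in 2 of 5 tested members, the calcium buffer gene Calb1 by 0.53 and the transcription factor gene Prox1 by 0.16 (4 fell when adjusted over the list alone). In Prox1, OIR replicate 2 stood above the rest at 150 CPM, and its call was lost within numbers 1 to 3 (adjusted p = 0.0702). The list median was -0.29, and -0.37 and -0.21 within the sets of numbers (camera adjusted p = 0.0314), with adjusted p = 0.106 with an estimated correlation, 0.0674 within numbers 4 to 6 and 0.0554 with a block for each replicate number.

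Rod photoreceptor genes showed small differences. Of 23 tested, 7 rose, 1 fell and 15 did not pass (13 and 2 when adjusted over the list alone). The cation exchanger gene Slc24a1 rose 1.16-fold, the transducin subunit gene Gngt1 1.12-fold and the phosphodiesterase subunit gene Pde6a 1.11-fold (edgeR adjusted p = 0.00288, 0.0197 and 0.0218). The phosphodiesterase subunit gene Pde6b fell by 0.13 on the log2 scale (edgeR adjusted p = 0.0244, chosen after its values were seen). The calls of Pde6a and Pde6b were lost without OIR replicate 1 (adjusted p = 0.0565 and 0.0516), that of Pde6a also without normoxic replicate 2 or 6 (0.0501 and 0.0515) and that of Pde6b without normoxic replicate 1 (0.0546). Within numbers 4 to 6, Slc24a1, Pde6a and Pde6b did not pass (adjusted p = 0.0784, 0.324 and 0.314), nor did Gngt1 within 1 to 3 (0.0521). With the lens covariate, Slc24a1, Pde6a and Pde6b did not pass (adjusted p = 0.0553, 0.189 and 0.159). The rod list did not pass (median 0.14, camera adjusted p = 0.101, or 0.488 with an estimated correlation). Its camera adjusted p was 0.0153 within numbers 1 to 3 (median 0.16), 0.202 within 4 to 6 (median 0.11) and 0.016 in limma on FPKM. The list also passed without an expression filter and with a block for the sets of numbers.

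Cone photoreceptor genes differed between the sets of replicate numbers. Pooled, Gnb3 (1.42-fold) and Thrb (1.10-fold) rose, Arr3, the cone arrestin gene, fell by 0.70 and 8 of 11 did not pass (also 2 and 1 when adjusted over the list alone). Its median was -0.03 while the camera test pointed higher (adjusted p = 0.878; 0.968 with an estimated correlation), and lower without normoxic replicate 4, 5 or 6 (0.879, 0.775 and 0.763). Within numbers 1 to 3 the list was lower (median -0.29, camera adjusted p = 0.00259) and within 4 to 6 higher (0.27, adjusted p = 1.6e-04). Camera's test of the difference itself gave an adjusted p of 4.3e-17. It used the preset correlation only, between sets chosen after seeing the data. The correlation estimated for this list was 0.5, so that p-value may be far too small. The log2 fold change of Arr3 differed between the sets by 1.40 (edgeR interaction adjusted p = 2.5e-07). Without normoxic replicate 1, 2 or 3, Arr3 lost its call (adjusted p = 0.0548, 0.0501 and 0.0548), and Thrb lost its own without normoxic replicate 1 or 3 or OIR replicate 2, 3 or 4 (0.0618, 0.0634, 0.0595, 0.058 and 0.0545). Within numbers 4 to 6, Thrb did not pass (adjusted p = 0.428) and Arr3 was at 0.12 (0.202), and neither passed with the lens covariate (0.369 and 0.218).

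The list of retinal pigment epithelium and melanocyte genes also differed between the sets, in directions opposite to those of the cone genes. None of 10 passed the pooled test, over all genes or adjusted over the list alone, with a median of -0.09 although the camera test pointed higher (adjusted p = 0.985; 0.994 with an estimated correlation). The test pointed lower without normoxic replicate 1, 2 or 3 (0.682, 0.748 and 0.752) or OIR replicate 5 or 6 (0.896 and 0.963), and with the lens covariate (0.781). Within numbers 1 to 3 the list was higher in OIR (median 1.57, camera adjusted p = 1.2e-04), and within 4 to 6 lower (-0.45, adjusted p = 0.00351). The difference had a camera adjusted p of 9.2e-21, with the same limits as for cones and an estimated correlation of 0.62. Ttr, the transthyretin gene, had 28.5 ± 25.9 CPM in normoxic and 33.9 ± 12.2 in OIR libraries (edgeR adjusted p = 0.762; a log2 fold change of -0.044 with the lens covariate), and its log2 fold changes differed by -2.61 between the sets (interaction adjusted p = 3.0e-08). Across all genes, 1501 had fold changes that differed between the sets by this edgeR test.

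**Figure D4:**
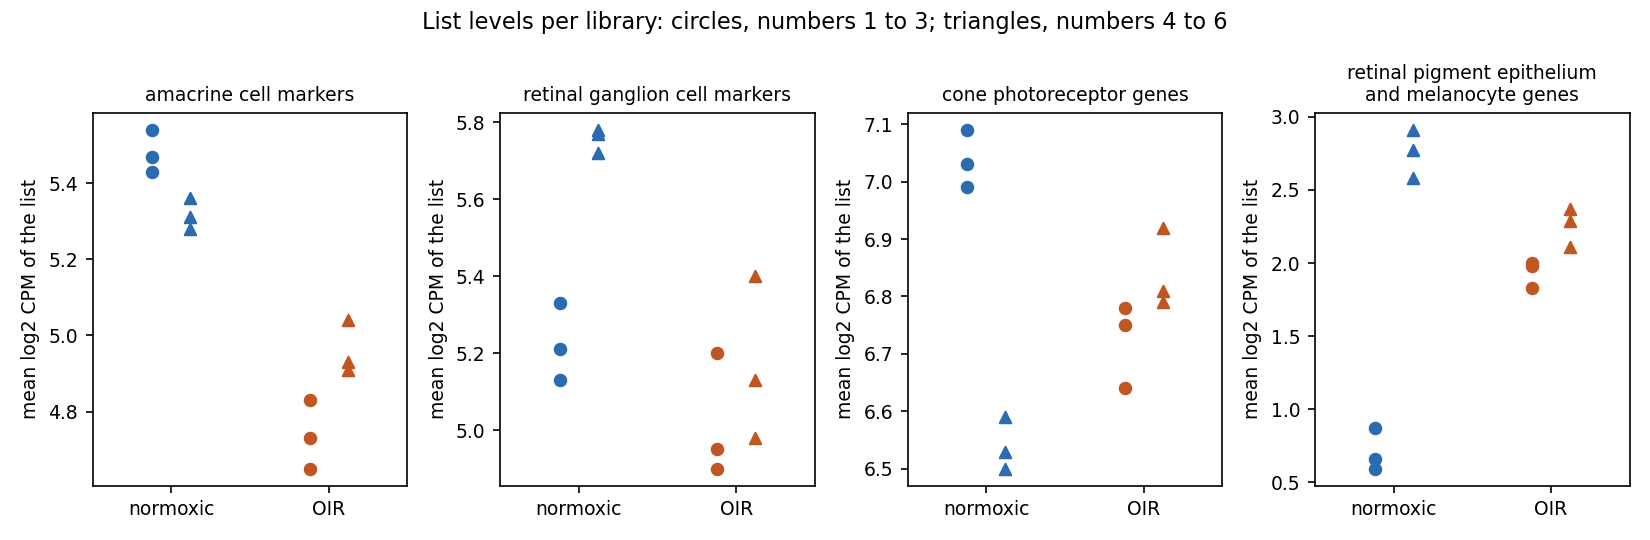
Mean log2 CPM (vertical axes) of the amacrine, ganglion cell, cone and pigment epithelium lists in each library of the normoxic and OIR groups, with circles for replicate numbers 1 to 3 and triangles for 4 to 6. The normoxic circles and triangles lie apart in each list, with the cone triangles below and the pigment epithelium triangles above the circles, where the OIR against normoxic medians within the 2 sets were -0.29 and 0.27 for cones and 1.57 and -0.45 for the pigment epithelium.

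Genes of cholesterol synthesis fell in 15 of 19 members and none rose (16 fell when adjusted over the list alone). Insig1, a sterol sensor gene, fell by 0.69 (edgeR adjusted p = 7.1e-08), and the list median was -0.36, with -0.33 and -0.34 within the sets of numbers (camera adjusted p = 3.7e-08; 0.00806 with an estimated correlation). Genes of p53 signalling and apoptosis rose in 6 of 11 members, with none falling (6 when adjusted over the list alone). The cell cycle inhibitor gene Cdkn1a rose 3.25-fold, and the list median was 0.47, with 0.56 and 0.40 within the sets (camera adjusted p = 1.7e-04; 0.0435 with an estimated correlation). Oxidative stress and ferroptosis genes, led by Hmox1, rose in 7 and fell in 1 of 13 members, over all genes and when adjusted over the list alone. The member that fell, the lipid-activating enzyme gene Acsl4 (-0.20, edgeR adjusted p = 0.0352, chosen after its values were seen), lost its call without normoxic replicate 4, 5 or 6 (0.0701, 0.0751 and 0.0735) or OIR replicate 3, 4, 5 or 6 (0.08, 0.058, 0.0529 and 0.0602), within numbers 1 to 3 (0.612) and with the lens covariate (0.127). The median over members was 0.21, with 0.28 and 0.13 within the sets (camera adjusted p = 0.00225; 0.0465 with an estimated correlation).

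Unfolded protein and integrated stress response genes rose in 6 of 12 members, among them the transcription factor gene Atf3 (4.75-fold), while Herpud1 fell by 0.27 (chosen after its values were seen), the same numbers as when adjusted over the list alone. Herpud1, an endoplasmic reticulum gene, was not past the test within numbers 4 to 6 (adjusted p = 0.586) or with the lens covariate (0.143). The list median was 0.18 (camera adjusted p = 0.0362), with adjusted p = 0.139 with an estimated correlation. For the list of unfolded protein and integrated stress response, the adjusted p was 0.0977 with the lens covariate, 0.0888 within numbers 1 to 3 (median 0.14), 0.0182 within 4 to 6 (median 0.18), 0.0542 without normoxic replicate 4, 0.0519 without OIR replicate 1 and 0.0509 with DESeq2. Immediate early genes rose in 4 of 9 members (also 4 when adjusted over the list alone), namely Nr4a1 (2.05-fold), Junb (2.98-fold), Fosb (1.74-fold) and Egr2. Egr2 had 16 normoxic and 344 OIR counts, a ratio of 21.3 (95% counting interval 12.9 to 37.7), with normoxic replicate 6 above the other normoxic libraries at 0.381 CPM. Fosb lost its call without OIR replicate 1 or 2 (adjusted p = 0.0653 and 0.0503) and with the lens covariate (0.166). The list median was 0.52, with 0.57 and 1.20 within the sets (camera adjusted p = 3.5e-04), with adjusted p = 0.118 with an estimated correlation.

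The circadian clock genes fell in 3 of 12 members, Per3 by 0.32, Dbp by 0.39 and Tef by 0.24, and none rose (3 when adjusted over the list alone). The clock list did not pass (median -0.15, camera adjusted p = 0.0778; 0.372 with an estimated correlation), with adjusted p = 0.00347 within numbers 1 to 3 (median -0.22), 0.275 within 4 to 6 (median -0.04), 0.037 without normoxic replicate 5 and 0.0417 without normoxic replicate 6. Dbp was not past the test within numbers 4 to 6 (adjusted p = 0.21) or with the lens covariate (0.0695). Nuclear genes of oxidative phosphorylation fell in 4 of 17 members, Ndufs1 (-0.21), Ndufv1 (-0.15), Uqcrfs1 (-0.14) and Cyc1 (-0.18), and none rose (4 when adjusted over the list alone). The call of Uqcrfs1 (edgeR adjusted p = 0.0358) was lost in 8 of the 12 comparisons that left out 1 library, namely without normoxic replicate 2, 4, 5 or 6 (0.0501, 0.0614, 0.0618 and 0.074) or OIR replicate 1, 2, 3 or 4 (0.0724, 0.0712, 0.072 and 0.0625). Within numbers 4 to 6, Uqcrfs1 and Ndufv1 did not pass (0.0643 and 0.356), nor with the lens covariate (0.105 and 0.0862). This list did not pass (median -0.05, camera adjusted p = 0.125; 0.645 with an estimated correlation), with medians of -0.04 and -0.06 within the sets and adjusted p = 0.0433 in limma on FPKM. Mitochondrially encoded mRNAs fell in 7 of 11 tested members (9 when adjusted over the list alone), with mt-Nd1 lower by -0.43 (edgeR adjusted p = 2.6e-05). Their median was -0.27 (camera adjusted p = 0.00217), with adjusted p = 0.31 with an estimated correlation, and -0.46 within numbers 1 to 3 against -0.05 within 4 to 6, where the list did not pass (0.202).

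The lens genes, which mark traces of another eye tissue, fell in 6 and rose in 1 of 14 tested members (11 and 1 when adjusted over the list alone). The one that rose was Cryab (1.36-fold, edgeR adjusted p = 2.1e-05), a small heat shock protein gene that is also transcribed outside the lens. The lens list median was -1.38, with -2.09 within numbers 1 to 3 and -0.51 within 4 to 6 (camera adjusted p = 0.032), with adjusted p = 0.417 with an estimated correlation, 0.0958 within numbers 4 to 6, 0.0729 with DESeq2, 0.0659 without normoxic replicate 3 and 0.578 with the lens gene level itself as a covariate. The red blood cell genes rose in 4 of 5 tested members (also 4 when adjusted over the list alone), Hbb-bs (2.17-fold), Hba-a1 (1.92-fold), Alas2 (1.85-fold) and Hbb-bt (1.68-fold). The globin genes have near-identical copies and are uncertain, and Hbb-bt lost its call without normoxic replicate 4, 5 or 6 (0.0599, 0.0561 and 0.0605) or OIR replicate 2 or 5 (0.0766 and 0.0599), within numbers 1 to 3 (0.0571) and with the lens covariate (0.085). The red blood cell list median was 0.89, with 0.64 and 1.39 within the sets (camera adjusted p = 0.032), with adjusted p = 0.195 with an estimated correlation, 0.0781 with a mean FPKM of at least 2 required and 0.0823 with DESeq2. The FPKM filter left out Alas2, so only part of the list was tested there.

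In all, camera called 26 of the 32 lists, 19 higher and 7 lower, and 15 of the 32 with a correlation estimated for each list. The 15 were the lists of hypoxia-inducible targets, endothelium, tip cells, pericytes, matrix, gliosis, microglia, cytokines, complement, amacrine cells, proliferation, astrocytes, p53, oxidative stress and cholesterol synthesis. For lists past the test in only 1 set of replicate numbers, the camera test of the difference between the sets gave an adjusted p of 3.0e-04 for Muller glia, 9.9e-10 for mitochondrial mRNAs, 0.00903 for clock genes, 0.0253 for lens genes, 0.0765 for rods, 0.108 for horizontal cells and 0.983 for the unfolded protein response. It used the preset correlation only. For lists past in both sets in the same direction, it gave 6.5e-10 for immediate early genes, 2.9e-09 for gliosis, 2.2e-08 for glycolysis and 2.7e-06 for amacrine cells. Ganglion and bipolar cells, astrocytes, tip cells, interferon, matrix, oxidative stress and red blood cells also passed. Hypoxia-inducible targets, endothelium, barrier genes, pericytes, microglia, cytokines, complement, proliferation, p53 and cholesterol synthesis did not. Of 3873 annotation terms, each tested among the genes that rose and among those that fell (one-sided Fisher's exact test, adjusted p under 0.05), 969 were enriched among the former and 277 among the latter. Angiogenesis genes rose in 112 of 217 members, where 35.3 were expected (adjusted p = 1.2e-30), and genes of collagen-containing extracellular matrix in 126 of 230, where 37.4 were expected (adjusted p = 5.2e-38). Genes of the inflammatory response rose in 109 of 198 members, where 32.2 were expected (adjusted p = 5.1e-33). Glutamatergic synapse genes fell in 202 of 459 members, where 67.9 were expected (adjusted p = 5.6e-49), and voltage-gated ion channel genes in 63 of 112, where 16.6 were expected (adjusted p = 1.0e-21). These 5 terms passed in the same direction within either set of replicate numbers.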

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

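The tests of library size, a shared batch, a mislabelled or mixed library, a strain variant and RNA of an OIR library were chosen only after the result was seen. Among 314 groups of 6 libraries scanned, 20 had 1 library far from the rest, where chance flags about 1 in 20 groups. The scan included Tpm3-rs7, Rps3a2, Nmnat1 and Rbp7, chosen after their values were seen, so this count is no test against chance. Normoxic replicate 6 stood above the other normoxic libraries in Esm1 (0.163 CPM) and Egr2 (0.381 CPM), normoxic replicate 3 in Ccl2 (0.114 CPM) and normoxic replicate 5 in Cdk1 (2.00 CPM). OIR replicate 2 stood above the other OIR libraries in Sec14l5 (4.13 CPM), Egln3 (39.7 CPM) and Prox1 (150 CPM), and OIR replicate 1 below them in Grm6 (157 CPM). OIR replicate 6 was low in Laptm5 (16.2 CPM) and in the mean log2 CPM of the interferon response list (2.23), and high in Chrna6 (95.1 CPM). OIR replicate 3 had the largest total, 21.6 Mcounts (mega-counts).

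Tpm3-rs7, Rps3a2, Nmnat1 and Rbp7, chosen after their values were seen, were raised in OIR replicates 1 to 5 and at the normoxic level in OIR replicate 6 (2.38, 3.74, 7.48 and 0.113 CPM). Normoxic replicate 4 stood above the other normoxic libraries in the same genes (11, 9.77, 13.8 and 1.59 CPM) and below them in Tpm3 (119 CPM). A mislabelled or mixed library as the whole cause is argued against by genes changed at least 2-fold without OIR replicate 6. In it they lay a median 79.9% of the way from the normoxic to the OIR level (quartiles 59.2 and 95.7). The medians of OIR replicates 1 to 5 were 95 to 106%. OIR replicate 6 was thus nearer to normoxic. A partial mix with normoxic RNA would leave the 4 genes part of the way too. Their means were 58.2, 52.1, 38.5 and 5.66 CPM in OIR replicates 1 to 5. In the normoxic libraries other than replicate 4 they were 2.68, 2.98, 7.8 and 0.242 CPM. OIR replicate 6 lay at the normoxic level, which argues against a partial mix as the cause for these 4 genes. Some mixing in the library as a whole is not excluded. RNA of an OIR library in normoxic replicate 4 is argued against by Esm1, Adm and Gfap. They lay there at most 1.04% of the way from the mean of the other normoxic libraries to that of OIR replicates 1 to 5. The 4 genes lay at 13.8 to 24.9%. Reads shared with a near-identical parent gene may account for Tpm3-rs7, since in OIR replicate 6 Tpm3 gained 105% of the CPM that Tpm3-rs7 lost. Rps3a1 gained 170% of the CPM that Rps3a2 lost there, more than sharing alone would give. It was at 250 to 297 CPM in OIR replicates 1 to 5, against 258 to 312 in normoxic libraries, so sharing stays open for Rps3a2. Nmnat1 and Rbp7 are not covered by this. A strain variant stays open, since 16 of the 90 genes with OIR replicate 6 as outlying library lay within 1 Mb of another. In 1000 random sets, the median was 12 and the 95th percentile 20. This count could not test the 4 genes themselves. It took only genes with OIR replicate 6 as outlying library, so a variant that parts the OIR group from the normoxic group was not tested. The design could not tell such a variant from OIR itself. Nmnat1 and Rbp7 lie within 1 Mb of each other on chromosome 4 (from 149552029 and 149534144). Tpm3-rs7 and Rps3a2 lie farther apart on chromosome 14 (from 113552040 and 88360453). If their reads came from the parent genes, these positions would not bear on a variant. No biological explanation was tested.

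Normoxic replicates 1 to 3 differed from normoxic replicates 4 to 6 in 4613 genes, 2307 higher and 2306 lower in the latter (edgeR's quasi-likelihood test), where the highest of the other splits gave 0; the 10 possible splits (1 with as many) are too few for a share under 0.05. Library size is argued against, since the totals differed by 0.387 Mcounts with an SD of 0.701 Mcounts. Gene length or GC bias as the whole cause is argued against, since 84.7% of the genes remained past the threshold after a correction for both. A batch shared by both groups stays open: the differences of 4 to 6 minus 1 to 3 correlated across genes, which are not independent, with r = 0.086 between normoxic and OIR, against at most 0.095 for other splits, and OIR replicates 1 to 3 and 4 to 6 differed in 92 genes (at most 1 in other splits). The labels give no batch or date, and no biological explanation was tested.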

How the results depend on the processing

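The fits within replicate numbers 1 to 3 and 4 to 6, with a block for these sets and with library totals only were chosen only after the result was seen. The counts were genes changed in OIR against normoxic, genes higher in OIR, genes lower in OIR, genes changed at least 2-fold in OIR against normoxic, genes at least 2-fold higher in OIR, genes at least 2-fold lower in OIR, lists, annotation term enrichment (terms summed over both directions), annotation terms enriched among higher genes and annotation terms enriched among lower genes. Each stayed within 1.5 times its value with median-of-ratios factors, robust dispersion, DESeq2, library totals only, the block for the 2 sets and without any single library. The block for the 2 sets called 2 lists that had not passed in the main fit, rods among them, and ended no list call. Leaving out 1 library gave 5073 to 5870 genes, 1017 to 1148 at least 2-fold, 25 to 27 lists and 1226 to 1272 terms, with 5638 genes without OIR replicate 6 and 5566 without normoxic replicate 4. Of 121 genes followed, 119 kept their direction and side of the threshold with DESeq2 (1 lost its call, 1 gained one), 116 of the 117 tested in limma on FPKM (1 lost) and 103 within numbers 4 to 6 (15 lost, 1 gained, 2 reversed). The lens covariate left 103 (17 lost, 1 reversed), with Rbp7 (adjusted p = 0.0837) and Tpm3 (0.0875) among the lost. In limma it left 93 of 117 (24 lost), and those lost in limma alone were Dbhos (adjusted p = 0.145), Gngt1 (0.0609), Agt (0.0515), Hba-a1 (0.0565), Alas2 (0.0814), Per3 (0.0533), Slco1c1 (0.058), Tpm3-rs7 (0.0696) and Nmnat1 (0.0662). The share of calls that were higher ranged from 45.1% (quantile normalization) to 58.2% (numbers 4 to 6 only). The replicate block called 5675 genes, 5339 of them shared with the 5673, and ended the call of the horizontal cell list (adjusted p = 0.0554) and of Acsl4 (0.066) but no other named call. Libraries with the same number did not deviate together (r from -0.035 to 0.13), and 2 normoxic and 3 OIR libraries correlated best with their own number. Without a filter, 278 genes were at least 2-fold lower and 2333 terms passed (1767 higher, 566 lower). A mean FPKM of at least 2, which tests fewer genes, gave 1968 higher genes, 316 at least 2-fold (288 and 28) and 776 terms (546 higher). The lens covariate gave 3443 genes (1957 and 1486), and in limma 2840 (1503 and 1337), 237 at least 2-fold (224 and 13). As the lens gene level itself differed between the groups, these fits cannot tell an effect of lens RNA from the group difference. The pseudocount shrinks the folds of low genes, so limma on FPKM gave 281 at least 2-fold (259 and 22), with pseudocount 0.1 676 (576 and 100) and with 0.5 448 (406 and 42). Other limma fits gave 276 (257 and 19) with no filter, with 2215 terms (1698 and 517); 216 (199 and 17) at a mean FPKM of at least 2, with 1787 higher genes and 703 terms (486 higher); 287 (265 and 22) rescaled; 284 (263 and 21) with median-of-ratios factors; 276 (251 and 25) with quantile normalization; 295 (272 and 23) with array weights; 281 (259 and 22) with robust eBayes; and 278 (258 and 20) with a replicate block. Numbers 1 to 3 only gave 7226 genes, with 405 at least 2-fold lower, and numbers 4 to 6 only, with as many libraries, 3671 genes (1536 lower). The correlation estimated per list left 15 lists, 2 of them lower. Ttr reversed with the lens covariate (-0.044) and within numbers 4 to 6 (-0.28). The list of retinal pigment epithelium and melanocyte genes reversed with the lens covariate (adjusted p = 0.781), DESeq2 (0.673) and numbers 4 to 6 (0.00351), and ranged from 0.597 to 0.971 without 1 library. The list of lens genes reversed in limma with the lens covariate (0.547), that of cone photoreceptor genes within numbers 1 to 3 (0.00259; 0.537 to 0.963 without 1 library) and Arr3 within 4 to 6 (0.12). For the reversals and the counts within numbers 1 to 3 and 4 to 6 the cause was not tested. Few counts limit Esm1, Ccl2, Kcne3, Actg2, Mrc1 and Egr2, whose ratios have wide intervals.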

Other observations

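The tests of the inner neuron markers were chosen only after the result was seen, as was the use of an estimated correlation in the splits of the lists, added once the splits with a preset correlation had been counted. Genes of the cytosolic ribosome rose together in OIR, 36 of 52 where 8.45 were expected (one-sided Fisher's exact test, adjusted p = 4.1e-15), and none fell. Fau, Rps2 and Rps19, chosen after their values were seen, rose by 0.39, 0.43 and 0.44 on the log2 scale (edgeR adjusted p = 3.1e-05, 6.1e-05 and 7.2e-05), each higher in 6 of 6 OIR libraries than in any normoxic one. Within replicate numbers 1 to 3 and 4 to 6, 37 and 33 members rose. Ribosomal protein genes have many processed pseudogenes, so their counts are less certain.

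Genes of the AMPA glutamate receptor complex fell in 23 of 27 members, where 3.99 were expected (adjusted p = 1.3e-13), with 24 and 14 within numbers 1 to 3 and 4 to 6. Those of the GABA-ergic synapse fell in 58 of 92, where 13.6 were expected (adjusted p = 2.3e-23). The AMPA receptor subunit genes Gria3 and Gria4 fell by 0.64 and 0.47 on the log2 scale, the GABA receptor subunit gene Gabrb1 by 1.08 and Hap1, a huntingtin-associated protein gene, by 0.74 (edgeR adjusted p = 1.3e-07, 1.6e-06, 1.9e-07 and 1.3e-08). These genes were chosen after their values were seen, and the groups did not overlap in any of them.

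The 51 markers of bipolar, amacrine and ganglion cells had a median log2 fold change of -0.42 in OIR. Dilution by RNA of cells other than rods, as the whole cause, is argued against, since it would lower rod genes alike. The median of 23 rod genes lay 0.57 above that of these markers (permutation test across genes, which are not independent, p = 1.0e-05, the smallest it can give). Dilution by a larger share of rod RNA stays open. It would leave rod genes higher, and their median was 0.145, so this comparison cannot decide on it. It would also lower cone genes, whose median was -0.03 pooled, -0.29 within numbers 1 to 3 and 0.27 within 4 to 6. The cone genes went with it in the first set and against it in the second, so they do not decide on it either. The difference within the normoxic group as the whole cause is argued against by medians of at most -0.29 within either set of replicate numbers. The scaling of the libraries stays open: the median was at most -0.42 over 3 scalings, but these moved the median of all genes by only 0.00892, too little for a test. A difference between OIR and normoxic retinas in the inner neurons stays among the open explanations, as untested.

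Chance was weighed with 100 of the 462 splits of the 12 libraries into 6 and 6. Chance assignment of single libraries can be excluded for the 5673 genes, the 1052 changed at least 2-fold and 1246 terms summed over both directions. For each, 1 split gave as many, the real one, and the highest other gave 0. Chance between sets of libraries is not excluded. The splits moved libraries singly, while normoxic replicates 1 to 3 differed from normoxic replicates 4 to 6 in 4613 genes. For the 26 lists with a preset correlation this count leaves chance open, since 8 splits gave as many and the highest other gave 28. The 7 others among the 8 kept 4 or 5 libraries of a group together, and so held part of the difference between OIR and normoxic. The 44 splits that kept 3 together, a grouping made after the counts were seen, gave 0 to 9 lists. With an estimated correlation, the 15 lists were reached in 1 split, the real one (highest other 0). Chance assignment of single libraries can thus be excluded for them, and chance between sets of libraries cannot.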
